A study of Mus musculus with 4 samples.

How the data were processed

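Livers of C57BL/6N mice, 1 mouse for each combination of treatment (control or ethanol) and sex, were measured by 10x Genomics 3′ single-cell RNA sequencing in 4 libraries. Per the labels, suspensions were checked for viability before loading, libraries were made with GEM-X v4 chemistry and sequenced on an Illumina NovaSeq instrument. The deposited matrices hold raw UMI counts per gene and barcode for 33696 genes. According to the series text, the authors aligned reads and counted UMIs with Cell Ranger 8.0.1 against the 10x Genomics mouse reference on GRCm39, and the submitters' processing notes give the build as GRCm39. The matrices hold barcodes called as cells, 42228 in all with 406991593 UMIs. Gene positions are on GRCm39 from GENCODE M39, a later annotation than that of the alignment reference, and were found by identifier for 113 of 113 genes looked up.

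Cells were kept with at least 500 UMIs, at least 300 genes and at most 30% mitochondrially encoded UMIs, which left 7887, 9971, 12264 and 10618 barcodes in control male, ethanol male, control female and ethanol female. The highest-scoring 0.4% per 1000 barcodes by Scrublet score were removed as doublets, 256, 413, 614 and 478 cells, leaving 38979. Counts were scaled to 10000 per cell and log-transformed, 2000 highly variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered by the Leiden method at resolution 1 without integration (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, Python 3.11.15). Of 43 clusters, 32 were named from fixed markers of 19 classes, at least 3 markers being needed, and 11 clusters with 4461 cells stayed unnamed. Among these, clusters 21, 26, 34 and 35 were left unnamed by hand. Cluster 21 scored best as plasma cells, with 73, 90, 231 and 106 cells in control male, ethanol male, control female and ethanol female. It was left unnamed because B cell markers were in more of its cells, so no plasma cell class was tested. Cluster-defining genes are not reported as results of a comparison.

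UMIs were summed per library and class. A class was tested when every library held at least 30 cells, which gave 10 classes. Hepatocytes fell short, so the comparisons and 15 gene lists meant for them could not be run. Ethanol was tested with the edgeR 4.0.16 quasi-likelihood F-test (robust, R 4.3.3, limma 3.58.1) with sex as an additive term, TMM scaling, filterByExpr by treatment with a minimum count of 10, and a two-sided Benjamini-Hochberg adjusted p threshold of 0.05. This leaves 1 residual degree of freedom, so the fit borrows a spread shared across genes. The p-values rest largely on that shared spread in these libraries, not on each gene's own spread between animals. Within a sex, 1 library stands against 1, so log2 ratios of TMM-scaled CPM with a prior count of 0.5 are given without a test. Shares have exact Clopper-Pearson 95% intervals. Of 38 gene lists, 23 were counted in at least 1 class. For each, the members that rose, fell or did not pass were counted, over all genes and adjusted over the list alone, and the median log2 ratio per sex was placed among 10000 random lists matched on expression in 20 bins. Lists of mitochondrially encoded, haemoglobin, hepatocyte, neutrophil and immediate early genes track RNA quality, dissociation and RNA of other cells. A member was marked as one that free RNA could carry when its mean CPM in the class was under 0.25 of that over all kept cells. Folds against libraries with 0 UMIs use a floor of 3 UMIs over the group, and intervals and floors cover counting error only.

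The classes, markers, lists, tests, filters and the rule for naming genes were set before the data were examined. Clusters 21, 26, 34 and 35 were left unnamed after their leading genes were seen. Named genes are the highest and lowest by fitted log2 fold change among called genes with the same sign in both sexes and at least 50 UMIs in the higher treatment, 10 each way in Kupffer cells, 10 in total in monocytes, neutrophils and sinusoidal endothelial cells and up to 3 each way in the others, without predicted or clone names. List members shown are those with the smallest p-values. The sex comparison in classes other than hepatocytes, the counts of IgA-rich barcodes and the T cluster tests were added after seeing the data.

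The fit was tested on simulated data with 200 changed genes per class, all with enough expected UMIs. The same dispersion of 0.05 was used for every gene and class. Coefficients of variation fitted to the data ran from 0.081 in B cells to 0.2898 in Kupffer cells, so recovery in Kupffer cells is likely overstated. It recovered 17% of 2-fold and 95% of 4-fold changes at the Kupffer depth, 24% and 90% at the monocyte, 22% and 95% at the neutrophil, 22% and 99% at the sinusoidal and 4% and 79% at the cholangiocyte depth. Alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, no sex term, each library left out in turn, no doublet removal, a stricter cell filter, Leiden resolution 0.5, equal cell numbers, genes free RNA could carry left out, another prior count and CPM without TMM. With 3 libraries the fit used treatment only, and the lone library of a treatment was assumed to vary like the other arm.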

Results

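Single-cell transcriptomes were collected from whole-liver suspensions of 4 C57BL/6N mice aged 8 to 10 weeks, after 2 weeks in the NIAAA ethanol-feeding model or its control arm. NIAAA feeding gives mice an ethanol-containing liquid diet and is used as a model of alcohol-associated liver disease. The groups were control male, ethanol male, control female and ethanol female, with 1 mouse in each. In that order the libraries held 8113, 10359, 12508 and 11248 barcodes and 62691282, 108542322, 123497694 and 112260295 UMIs, against a target of 10000 cells per library. After filters and doublet removal, 7631, 9558, 11650 and 10140 cells were kept, with median depths of 5033, 8738, 8623 and 9036.5 UMIs per cell. Median mitochondrial percentages of the kept cells were 3.87, 2.43, 2.25 and 2.39. The sex labels matched the transcripts in all 4 libraries. Xist stood at 0.0967 and 0.0557 CPM in control and ethanol males and at 845 and 901 CPM in control and ethanol females. Ddx3y stood at 158 and 218 CPM in the males and at 0.0894 and 0.170 CPM in the females. Eif2s3y, Kdm5d and Uty were at 106 to 114, 32.0 to 33.7 and 132 to 156 CPM in males, and at 0, at most 0.0179 and at most 0.0325 CPM in females.

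Ethanol and control livers were first compared for the cell classes they yielded, since infiltration of the liver by leukocytes and loss of resident cells are open questions in this model. T cells made up 43.9% (95% interval 42.9 to 44.9) of the ethanol male library and 49.5% (48.5 to 50.5) of the ethanol female library, against 9.04% (8.41 to 9.71) and 13.9% (13.3 to 14.5) of their controls. Sinusoidal endothelial cells made up 39.4% (38.3 to 40.5) of the control male and 9.18% (8.66 to 9.71) of the control female library, against 2.74% (2.42 to 3.09) and 2.14% (1.87 to 2.44) with ethanol. Monocytes or monocyte-derived macrophages were at 6.29% and 5.68% in control males and females and at 1.46% and 1.28% with ethanol. Neutrophils were at 9.63% and 3.61% in controls and at 1.86% and 1.70% with ethanol. Kupffer cells, the resident macrophages of the liver, were at 1.23% and 1.25% in controls and at 0.314% and 0.957% with ethanol. Conventional dendritic cells were at 4.19% and 2.17% in controls and at 7.05% and 5.51% with ethanol, and plasmacytoid dendritic cells at 3.09% and 1.51% against 7.82% and 6.44%. B cells were at 11.4% and 48.5% in control males and females, and at 8.65% and 7.72% with ethanol, so the control female library held far more B cells than any other. NK cells or ILC1 were at 7.61%, 7.48%, 7.49% and 8.10% in control male, ethanol male, control female and ethanol female. Among cells other than B cells, an alternative chosen after seeing the data, the female difference of the NK or ILC1 share turned from 0.603 to -5.77 percentage points. At the coarser clustering the male difference turned from -0.133 to 1.65 points, and the vascular endothelial difference moved from 0.688 to 3.71 points in males and from 0.0522 to 3.10 in females. Within the T class, the cluster led by Atp8a2, Il4 and Zbtb16 held 0.432% and 1.14% of control and 9.07% and 13.4% of ethanol cells, in males and females. The cluster led by Gzmk, Cd8a and Pdcd1 held 0.996% and 0.867% of control cells, 14.0% of ethanol male cells and 2.49% of ethanol female cells. Hepatocytes numbered 10, 8, 16 and 3 cells, too few to test. Unnamed clusters held 6.95%, 16.9%, 6.18% and 15.7% of cells. Intervals are exact Clopper-Pearson intervals and cover counting error only. With 2 libraries against 2, an exact two-sided test cannot go below p = 0.333, so no share was tested. The control male library was the shallowest, at 5033 median UMIs, yet held the highest sinusoidal endothelial share. Sinusoidal endothelial cells held few UMIs, with medians of 2836, 1223, 2129 and 958, so recovery and depth may affect their share, which was not tested.

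**Figure D1:**
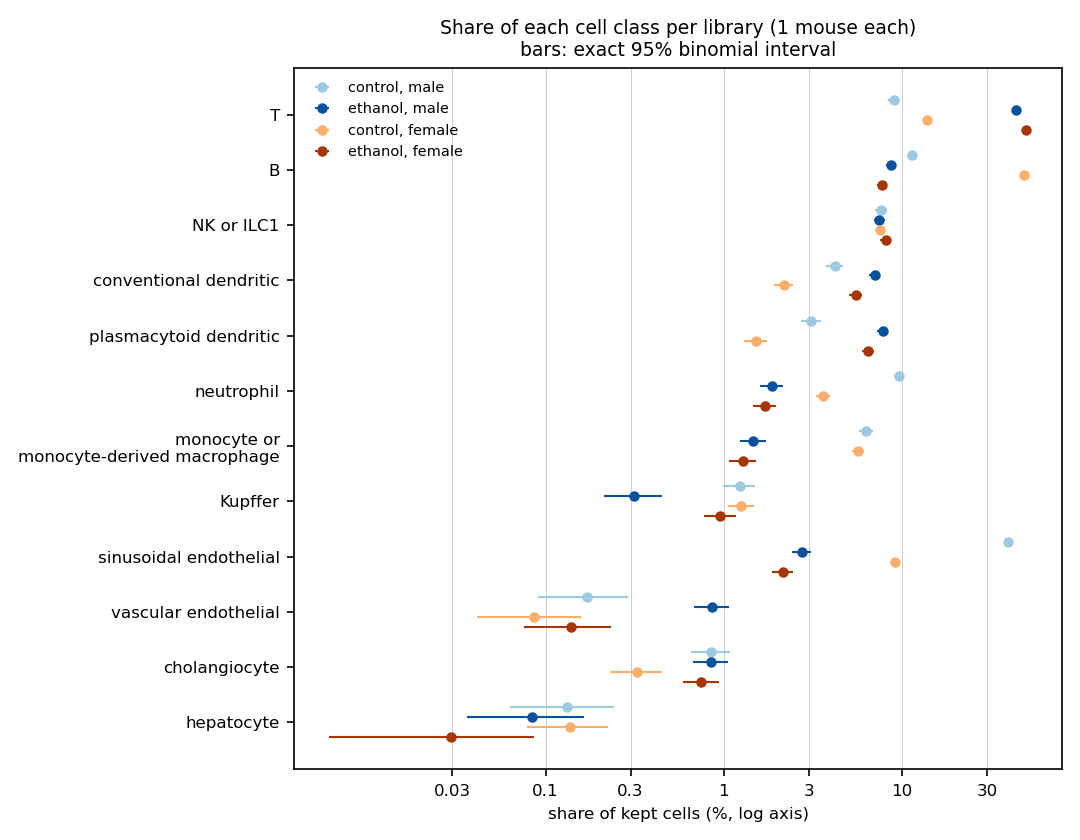
Percentage of kept cells in each cell class per library on a log axis, 1 mouse per library, with exact 95% binomial intervals as bars. T cells sit at 43.9% and 49.5% in the ethanol libraries against 9.04% and 13.9% in the controls, and sinusoidal endothelial cells at 2.74% and 2.14% against 39.4% and 9.18%.

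Kupffer cells were compared next, because macrophage-driven inflammation is the subject named in the series title. With ethanol, Kupffer cells carried more Thbs1, Ccl9 and Vegfa and less of the resident-macrophage transcripts Timd4 and Marco. Thbs1 (ENSMUSG00000040152, chromosome 2, 117941974 to 117957616) rose from 16.3 to 534 CPM in males and from 7.76 to 137 CPM in females, a log2 fold change of 4.60 ± 0.49 (SE, n = 2 libraries per treatment; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00956). Timd4 (ENSMUSG00000055546, chromosome 11, 46701620 to 46735177) fell by 2.91 ± 0.41 on the log2 scale (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0180), lower with ethanol in both sexes. These p-values rest largely on a spread shared across genes in these 4 libraries only, with 1 residual degree of freedom. Of 6319 genes tested, 45 passed, 29 higher and 16 lower, and 681 had an unadjusted p under 0.05. The other highest genes were Ccl9 (log2 4.33), Vegfa (4.18), Sdc4 (3.23), Gpr35 (3.03), Rab11fip1 (3.01), Dusp5 (2.96), Cdkn1a (2.87), Mmp19 (2.83) and Socs3 (2.64). The lowest included Cxcl13 (-5.18, with 0 UMIs in the ethanol male and 6 in the ethanol female library), Cd55 (-4.22), Ptprm (-3.86), Bank1 (-3.59), Pou2f2 (-2.72) and Itsn1 (-2.70). Pcolce2, Paqr9 and Hbegf, also called, had 1, 2 and 3 UMIs over the ethanol libraries, and their CPM was 72.2-fold (95% counting interval 12.9 to 2862), 22.2-fold (6.07 to 185) and 21.3-fold (7.2 to 104) lower. The Kupffer identity list of 19 measured genes had 0 that rose, 2 that fell and 17 that did not pass, and 10 fell adjusted over the list alone. Its median log2 ratio was -1.59 in males and -0.79 in females, at percentiles 0 and 0.1 of 10000 matched random lists. The 2 that fell were Timd4 and Marco (-2.64). Marco went from 29.4 to 8.55 CPM in males and from 2257 to 314 CPM in females. Of 19 phagocytosis and complement genes, 0 rose, Timd4 and Cfp (-1.85) fell, 17 did not pass, and adjusted over the list alone 1 rose and 2 fell. Of 16 lipid-associated macrophage genes, Plin2 (1.76) rose and 15 did not pass, with 2 rising and 0 falling adjusted over the list alone. Of 12 reparative macrophage genes 2 rose (Vegfa and Socs3), 0 fell and 10 did not pass, with 3 rising and 2 falling adjusted over the list alone. No member passed by edgeR among 28 inflammatory cytokine and NF-kB genes (Nlrp3 1.37, Cxcl2 0.92), 12 Fc and IgA receptor genes (Fcgr2b 1.40, Ptpn6 -1.08), 25 interferon response genes, 18 antigen presentation genes, 17 NRF2 genes, 16 ER stress genes (Calr -1.57, Hspa5 -1.10), 10 iron genes, 16 lysosome genes, 24 immediate early genes or 8 proliferation genes (Top2a 2.46, Mki67 2.40). Adjusted over the list alone, the counts that rose and fell were 3 and 1 for the inflammatory (0 and 0 without the 1 member that free RNA could carry), 2 and 1 for the immediate early, 0 and 1 for the ER stress and 6 and 0 for the proliferation list, and 0 and 0 for the 6 others. Median log2 ratios in males and females were 0.42 and 0.00 for the inflammatory, -0.04 and -0.35 for the Fc and IgA receptor, -1.03 and -0.13 for the interferon and 3.14 and 1.54 for the proliferation list. Mitochondrially encoded genes had 0 of 13 past the test, with medians of -0.27 and -1.05. Hepatocyte RNA (0 of 4) and neutrophil RNA (0 of 3) had none past the test, and 2 and 1 members fell adjusted over the list alone. The class held 94, 30, 146 and 97 cells with median UMIs of 2560, 1430, 1694 and 1345, and its high-UMI cluster led by Cd5l and Clec4f held 12.8%, 3.33%, 17.8% and 1.03% of it. Per cell, that cluster held a median of 29310 UMIs against 1457 in the other Kupffer cluster, so it weighs more in summed UMIs than in cells. Marco and Timd4 are in its top 10, so their fall is not separated from the shift between clusters. Ms4a7, a fixed marker of the monocyte class, is in the top 10 of the other Kupffer cluster. Thbs1 is in the top 10 of the monocyte cluster led by F13a1. Leaving out the ethanol male, control female or ethanol female library gave 9, 3 and 288 calls, with Marco at 2.42 without the control female, and Cxcl2 at -0.16 and Fcgr2b at -0.07 without the ethanol male. Of the 20 named genes, 17, 17, 7 and 2 lost their call without the ethanol male, control female, control male and ethanol female library. Fits with a library left out hold no sex term, and Marco differed strongly by sex, so its value of 2.42 mixes sex with ethanol. edgeR gave 0 calls with RLE size factors (654 at an unadjusted p under 0.05), 0 without the sex term (369) and 0 without doublet removal (688), while DESeq2 gave 41.

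Monocytes or monocyte-derived macrophages were compared as the recruited counterpart of Kupffer cells. With ethanol this class carried more complement C1q, MHC class II, Gpnmb and cell-cycle transcripts and less Cd177 and Chil3. Gpnmb (ENSMUSG00000029816, chromosome 6, 49013426 to 49047863) rose from 3.67 to 58.6 CPM in males and from 2.86 to 149 CPM in females, a log2 fold change of 4.94 ± 0.40 (SE, n = 2 libraries per treatment; edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.000445). C1qa (ENSMUSG00000036887, chromosome 4, 136623223 to 136626161) rose by 3.41 ± 0.22 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 7.09e-05), higher with ethanol in both sexes. Of 10815 genes tested, 1081 passed, 771 higher and 310 lower. The highest others were Arhgap22 (5.13), Dcstamp (5.10), Cd34 (4.66) and Sdc1 (4.59), and the lowest included Cd177 (-3.06) and Itga8 (-3.06). Lyz1, Nxpe5 and Cyp7b1 also fell, with 3, 2 and 2 UMIs over the ethanol libraries and CPM lower by 13.9-fold (95% counting interval 4.73 to 68.0), 12.8-fold (3.48 to 106) and 9.95-fold (2.71 to 83.0). Lyz1 is close to Lyz2 in sequence, so its counts are uncertain. Of 32 inflammatory cytokine and NF-kB genes, 15 rose, 0 fell and 17 did not pass, including Cxcl16 (2.78), Ccl4 (2.01), Cxcl2 (1.64) and Tnfaip3 (1.6), and adjusted over the list alone 20 rose and 2 fell. Of 19 lipid-associated macrophage genes, 10 rose, 0 fell and 9 did not pass, including Mmp14 (3.55), Cd63 (3.13) and Plin2 (1.43), and adjusted over the list alone 12 rose and 1 fell. Of 14 reparative macrophage genes, 6 rose, 1 fell and 7 did not pass, with Il10 at 3.58, Axl at 2.58 and Chil3 at -1.16, and adjusted over the list alone 9 rose and 2 fell. Of 17 phagocytosis and complement genes, 7 rose, 2 fell and 8 did not pass, including C3ar1 (3.70) and C1qb (3.16), and adjusted over the list alone 9 rose and 5 fell. Antigen presentation had 9 of 19 genes that rose, 0 that fell and 10 that did not pass, including H2-Eb1 (2.98), H2-Aa (2.52) and Cd74 (1.87), and 12 rose and 0 fell adjusted over the list alone. Among 14 Fc and IgA receptor genes, Fcgr4 (1.74), Clec7a (1.03) and Fcgr2b (1.01) rose, 0 fell and 11 did not pass, and adjusted over the list alone 3 rose and 1 fell. In the interferon response list of 31, Oas2 (0.92) rose, Zbp1 (-0.69) fell and 29 did not pass, with 1 rising and 0 falling adjusted over the list alone. Proliferation genes rose in 11 of 16, with 0 that fell and 5 that did not pass, led by Rrm2 (4.56), Pclaf (4.56) and Stmn1 (3.77), and 13 rose adjusted over the list alone. Male and female medians were 1.04 and 0.60 for the inflammatory, 1.01 and 1.39 for the lipid-associated, 0.78 and 0.62 for the antigen presentation and 0.81 and -0.21 for the interferon list. All 13 mitochondrially encoded genes rose (mt-Co1 1.15), immediate early genes had 4 that rose and 1 that fell of 24, hepatocyte RNA had 0 of 13 past the test, haemoglobin RNA fell in 2 of 3 and neutrophil RNA in 1 of 5. The cluster led by F13a1, Lyz2 and Chil3 held 65.0% and 72.1% of the class in control males and females, and the cluster led by Pparg, Adgre4 and Ace held 74.3% and 56.2% with ethanol. These shares depended on the clustering. At the coarser resolution the Pparg cluster held 17 of 53 and 4 of 61 ethanol cells of the class. The class shrank there from 140 and 130 ethanol cells, and its median UMIs were 18606, 17308, 18745.5 and 19304. In control male, ethanol male, control female and ethanol female, the dendritic cluster led by Cd209a held 196, 402, 149 and 391 cells there. At resolution 1 it held 104, 315, 89 and 323. Cells were not followed between the resolutions, but part of the monocyte class may be grouped as dendritic at the coarser one. Fcgr4 is in the top 10 of the Pparg cluster, C1qa, C1qb and C3ar1 in that of a Kupffer cluster, and Arhgap22 in that of the dendritic cluster led by Cd209a. Of the 7 measured dendritic markers, Flt3 (2.07), Clec9a (2.27) and Ccr7 (1.65) rose in the class, and Cd209a (-2.48) and Naaa (-1.02) fell. Clec10a and Wdfy4 did not pass, and free RNA could carry Clec9a and Ccr7. Chil3 leads the F13a1 cluster and stood at -0.96 within that cluster alone, where it was still called. Median UMIs were 16251, 3281, 18132 and 4480 and median mitochondrial percentages 1.81, 7.33, 1.35 and 4.0, so depth and RNA quality differed with treatment. Leaving out the ethanol male or ethanol female library gave 157 and 204 calls, and 6 of the 10 named genes lost their call in each case, against 2 without the control male and 1 without the control female. DESeq2 gave 599 calls. With the mitochondrial percentage in place of sex, chosen after seeing the data, 23 genes passed and Chil3 stood at 0.38.

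Neutrophils, the early phagocytes of alcohol-associated hepatitis, were compared in the same way. With ethanol they carried more Lipg, Cdkn1a, Cxcl3 and Mmp8 and less Tnf, Ccl4 and Irf1. Lipg rose by 4.46 ± 0.48 on the log2 scale (SE, n = 2 libraries per treatment; edgeR with Benjamini-Hochberg adjustment, adjusted p = 8.98e-18), higher in both sexes. The small p-value of Lipg rests on a spread shared across genes, not on replicate mice. Of 7052 genes tested, 741 passed, 408 higher and 333 lower. The next highest were H1f0 (3.47), Prnp (3.04), Gpr55 (2.98) and Cdkn1a (2.78). The lowest included Stfa1 (-3.31), and Tmem202, Stfa2, Pira1 and Pigl fell to 2, 3, 2 and 3 UMIs over the ethanol libraries, with CPM lower by 12.7-fold (95% counting interval 3.39 to 107), 10.3-fold (3.42 to 51.1), 9.34-fold (2.46 to 79.1) and 7.99-fold (2.62 to 39.7). Stfa1, Stfa2 and Pira1 have near-identical copies, so their counts are uncertain. Of 27 inflammatory cytokine and NF-kB genes, 6 rose, 4 fell and 17 did not pass, with Cxcl3 at 2.77, Cd14 at 2.10, Ccl4 at -1.66 and Tnf at -1.92, and adjusted over the list alone 10 rose and 5 fell. Of 19 granule and maturity genes, 4 rose, 3 fell and 12 did not pass, with Mmp8 at 2.03, Lcn2 at 0.96 and Padi4 at -1.23, and the same counts adjusted over the list alone. Fc and IgA receptor genes had 0 that rose, 4 that fell and 8 that did not pass of 12, including Ptpn6 (-1.18) and Lgals3 (-1.07), with 0 and 4 adjusted over the list alone. Interferon response genes had 0 that rose, 4 that fell and 23 that did not pass of 27, including Irf1 (-1.53) and Cmpk2 (-1.35), with 7 falling adjusted over the list alone, or 4 without the 2 members that free RNA could carry. Immediate early genes rose in 8 of 22 (Egr1 2.16, Fos 1.34), with 0 that fell and 10 rising and 1 falling adjusted over the list alone. Proliferation genes rose in 2 of 4, though free RNA could carry 2 of the 4, mitochondrially encoded genes fell in 8 of 13, and hepatocyte RNA had 2 that rose and 2 that fell of 10. Median UMIs were 4805, 5779, 5527 and 5576. Leaving out the ethanol male or the ethanol female library gave 174 and 169 calls, with 4 and 3 of the 10 named genes no longer called, against 2 and 3 without the control male and the control female, the fit without doublet removal gave 350, and DESeq2 gave 200.

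Sinusoidal endothelial cells, which line the capillaries of the liver, were compared because their share was lower with ethanol. Those named as this class in the ethanol libraries carried more Ly6c1, Vwf, Lyve1 and cell-cycle transcripts and less Fcgr2b and Lama4. Ly6c1 (chromosome 15, 74915847 to 74920686) rose by 6.43 ± 0.51 on the log2 scale (SE, n = 2 libraries per treatment; edgeR with Benjamini-Hochberg adjustment, adjusted p = 7.06e-09), higher in both sexes, and is close in sequence to other Ly6 genes. Of 10425 genes tested, 3004 passed, 1661 higher and 1343 lower. The next highest were H3c3 (6.24), Pimreg (5.91), H2ac4 (5.82) and Ube2c (5.0), and the histone genes have near-identical copies. Hmga2, Colec10, Gpr157, Serpina1a and Cyp2e1 fell and had 0 UMIs in both ethanol libraries. Against a floor of 3 UMIs over the group they were at least 3.78-fold, 3.45-fold, 2.93-fold, 2.93-fold and 2.75-fold lower. Cyp2e1 is a fixed hepatocyte marker in the top 10 of the hepatocyte cluster. Its fall is not separated from that of hepatocyte RNA, which fell in 8 of 16 genes in this class. Of 20 sinusoidal identity genes, 4 rose, 12 fell and 4 did not pass, with Wnt9b at 3.26, Thbd at 2.88, Lyve1 at 2.63 and Fcgr2b at -1.68, and the same counts adjusted over the list alone. Of 20 endothelial activation and capillarisation genes, 10 rose, 2 fell and 8 did not pass, with Vwf at 3.62, Cd34 at 3.60, Nos3 at 1.63 and Lama4 at -1.81, and the same counts adjusted over the list alone. Interferon response genes rose in 11 of 29, with 0 that fell and 18 that did not pass, including Ifit1 (2.13) and Isg15 (2.11), and 15 rose adjusted over the list alone. Antigen presentation genes rose in 6 of 15, with 0 that fell and 9 that did not pass, including Tap1 (1.42) and H2-D1 (1.04), and the same counts adjusted over the list alone. Proliferation genes rose in 15 of 20, with 0 that fell and 5 that did not pass, including Mki67 (3.81) and Cenpf (3.78), and 16 rose adjusted over the list alone. Vwf and Wnt9b are among the genes that lead the vascular endothelial cluster, and Thbd is in its top 10, so markers of another endothelial type rose in this class. Ly6c1 leads an unnamed cluster with Mgp and Sema3g. A small cluster led by Cenpf, Ckap2 and Sdk1 held 0.466% and 0.561% of the class in controls and 4.96% and 3.69% with ethanol. In the ER stress list, Manf (1.57) rose and 15 of 16 did not pass, and immediate early genes rose in 7 of 25 (Hspb1 3.16, Klf2 1.62). Mitochondrially encoded genes fell in 10 of 13 (mt-Nd2 -1.12), hepatocyte RNA in 8 of 16, haemoglobin RNA in 3 of 3 and neutrophil RNA in 1 of 3. The cluster led by Stab2 and Cyp4b1 held 74.5% and 65.4% of the class in control males and females, and the low-UMI cluster led by Fam167b held 58.4% and 81.6% with ethanol, against 6.35% and 23.8% in controls. Lyve1 is in the top 10 of that low-UMI cluster. An unnamed cluster led by Iigp1, Cxcl9 and Sele had 10 sinusoidal markers detected but was not in the tested class. It held 317 and 331 ethanol cells in males and females, against 262 and 217 in the class, and 5 and 27 control cells. In fits chosen after seeing the data, 2963 genes passed with it added, and 2476 with the low-UMI cluster then left out. Leaving out the control male, control female or ethanol female library gave 411, 1103 and 629 calls, and 3 and 1 of the 10 named genes lost their call without the ethanol male and the ethanol female. DESeq2 gave 1382 calls. With the mitochondrial percentage in place of sex, chosen after seeing the data, 297 genes passed, and Cd34, Isg15, Ifit1 and H2-D1 stood at -0.81, -2.68, -2.08 and -0.74.

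**Figure D2:**
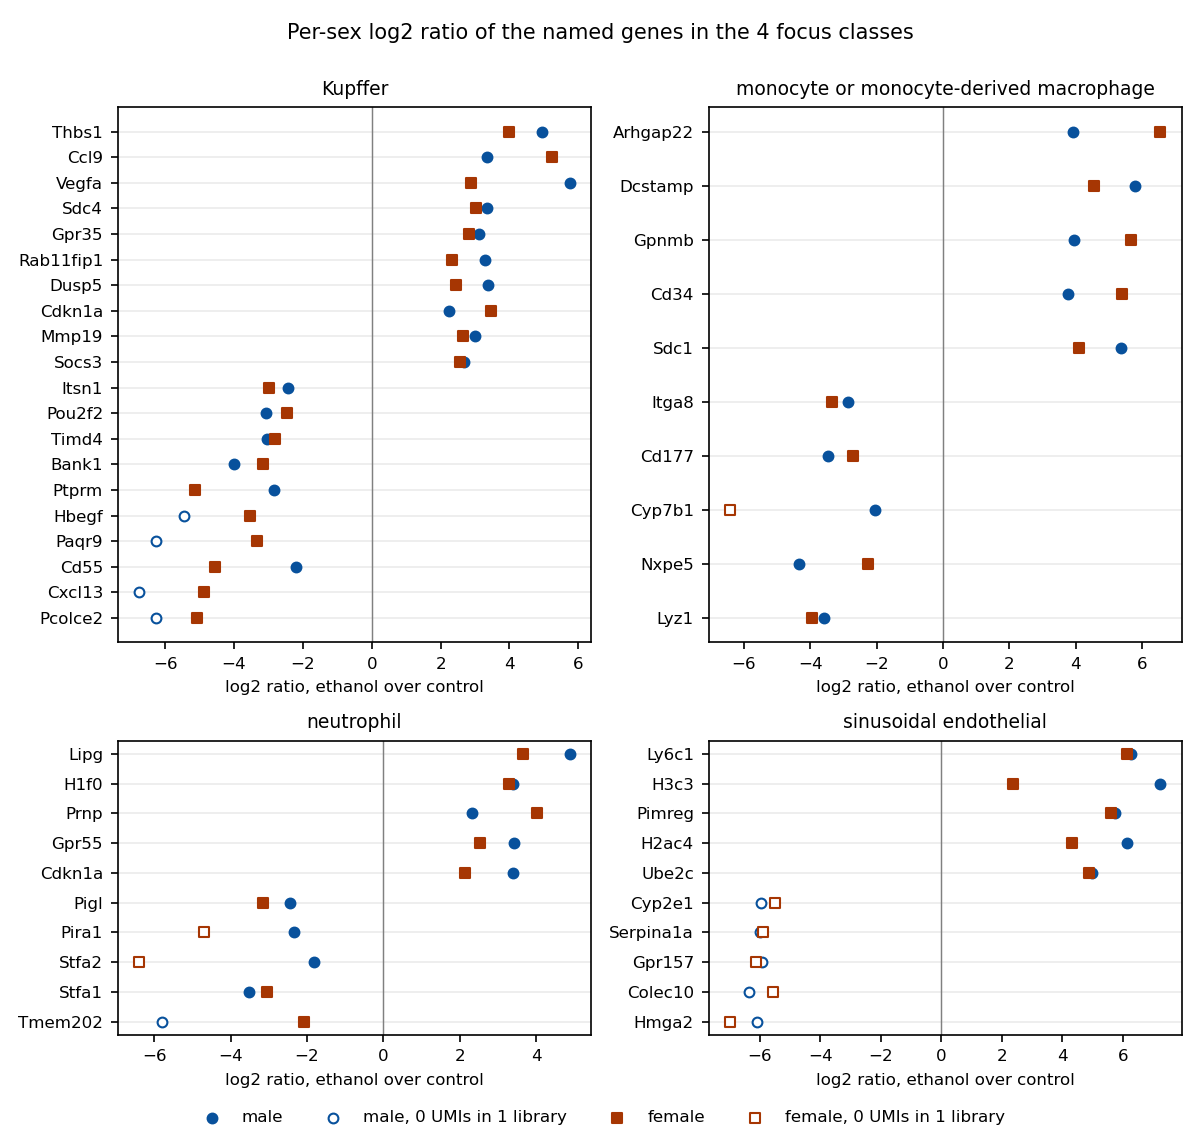
Log2 ratio of ethanol over control CPM within males (circles) and within females (squares) for the named genes of 4 cell classes, 1 library per group, open symbols where 1 of the libraries had 0 UMIs. Thbs1 in Kupffer cells lies at 4.96 in males and 3.99 in females, and Timd4 at -3.03 and -2.80.

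**Figure D3:**
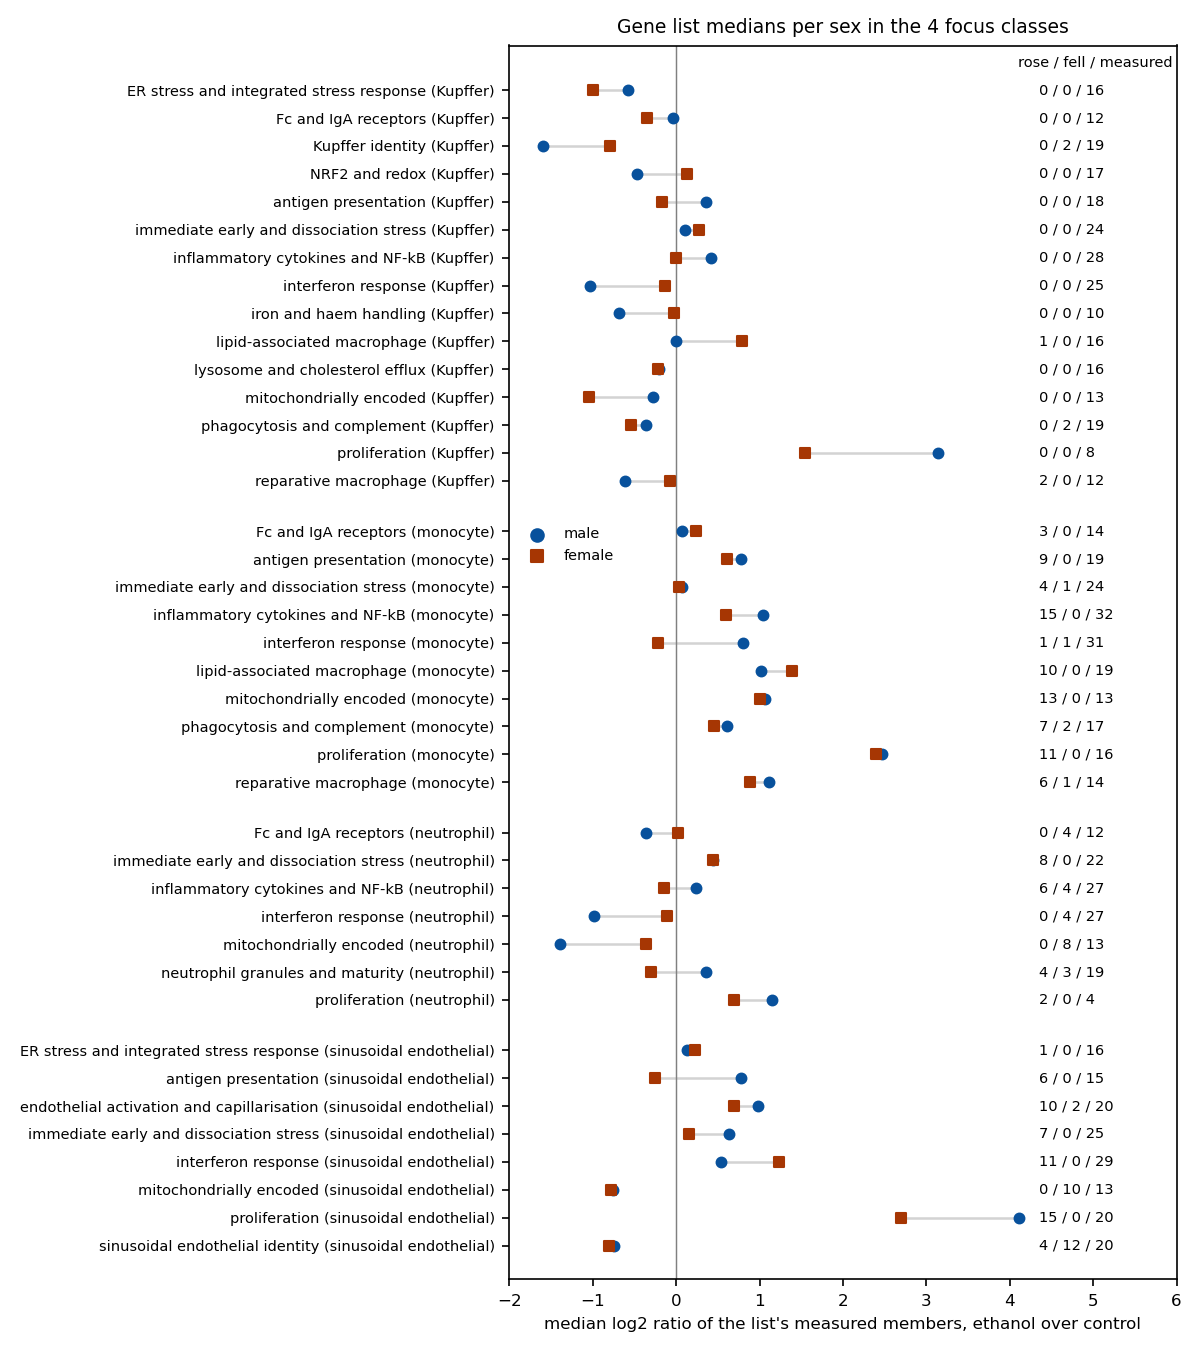
Median log2 ratio, ethanol over control, of the measured members of each gene list within males (circles) and females (squares) in 4 cell classes, 1 library per group, with the numbers that rose, fell and were measured at the right. The lipid-associated macrophage list in the monocyte class lies at 1.01 and 1.39, and the Kupffer identity list at -1.59 and -0.79.

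Lymphocyte, dendritic and bile duct classes were then compared to see how far the ethanol changes reached beyond phagocytes. NK cells or ILC1 carried less of several cytotoxic transcripts, with Klrg1 at -2.93, Gzmb at -1.99, Gzma at -1.81 and Prf1 at -1.53, and 2604 of 11905 genes passed (1351 higher, 1253 lower). Of 21 cytotoxic and exhaustion genes in that class, 3 rose, 8 fell and 10 did not pass, with the same counts adjusted over the list alone. Their median was -0.12 in males and -0.82 in females, at percentiles 10.9 and 0 of matched random lists. Cluster 6, led by Klra8, held 75.7% and 68.8% of the class in controls, and cluster 9, led by Klrb1b and Xcl1, held 65.9% of it in the ethanol male and 48.0% in the ethanol female library. Gzma and Prf1 are in the top 10 of the Klra8 cluster, which fell to 34.1% and 52.0% of the class with ethanol, so their fall is not separated from that shift. T cells had 636 of 14968 genes past the test (372 higher, 264 lower). Penk (3.81) and Serpina3f (3.37) rose, and Igfbp4 (-3.04) and Cma1 (-4.32) fell. Rorb, with 0 UMIs in both controls, was at least 13.8-fold higher against a floor of 3 UMIs over the group. Cma1 is in the top 10 of the Klra8 NK cluster and stood at 2.79 and 2.28 CPM in control male and female T cells. Of 22 cytotoxic and exhaustion genes in T cells, 3 rose (Fasl 1.13, Ctla4 1.10, Klrd1 1.02), Klrg1 (-1.29) fell and 18 did not pass, with 6 and 1 adjusted over the list alone. Interferon response genes rose in 3 of 31 (Rsad2 1.87), with 10 rising and 1 falling adjusted over the list alone. The T cluster led by Slc28a2b and Lef1 held 46.5% and 41.3% of the class in controls, against 9.79% and 20.6% with ethanol. Igfbp4 stood at 354 and 231 CPM in control male and female cells of that cluster, and at -1.55 tested within it. Its larger fall over the class is not separated from that shift. Ctla4 is in the top 10 of the Foxp3 cluster, which held 17.7% and 17.3% in controls and 23.4% and 19.9% with ethanol. Its rise is not separated from that shift either. The cluster led by Atp8a2 held 4.78% and 8.23% in controls and 20.6% and 27.1% with ethanol, in males and females. The cluster led by Gzmk held 11% in the control male and 31.9% in the ethanol male library, but 6.25% in the control female and 5.02% in the ethanol female. B cells had 1519 of 11519 genes past the test (889 higher, 630 lower). Of 19 antigen presentation genes in B cells, 1 rose, 8 fell and 10 did not pass, with H2-Oa at -0.78, H2-DMb1 at -0.66, H2-Ab1 at -0.56 and Cd74 at -0.51, and the same counts adjusted over the list alone. Conventional dendritic cells had 1526 of 11831 genes past the test (931 higher, 595 lower), with Selp (4.97) and Atp8b1 (4.94) higher and Cd207 (-3.65) and Ryr3 (-3.20) lower. Selp is a leading gene of the vascular endothelial cluster. Of 19 antigen presentation genes in them, 3 rose, including Cd80 (1.75) and Cd86 (1.21), 2 fell and 14 did not pass, with 4 and 2 adjusted over the list alone. Proliferation genes fell in 8 of 18 (Mcm5 -2.02, Mcm3 -1.91), with 10 falling adjusted over the list alone. Median UMIs of that class were 20944.5, 13639.5, 21726 and 3705 and median mitochondrial percentages 1.86, 2.53, 1.47 and 3.69, so depth and RNA quality differed with treatment. The Xcr1 cluster held 57.8% and 45.5% of that class in controls and the Cd209a cluster 46.7% and 57.8% with ethanol. Plasmacytoid dendritic cells had 2007 of 11504 genes past the test (1137 higher, 870 lower), and immediate early genes rose in 15 of 24 (Atf3 3.09, Nr4a1 1.51, Klf2 1.22) with 0 that fell. Their cluster led by Srgap3 held 19.9% and 2.84% of the class in controls and 40.3% and 28.6% with ethanol. Haemoglobin transcripts fell in that class (Hba-a2 -4.17, Hbb-bt -4.11), and Hba-a1 stood at 0.83 without the control male library. That fit holds no sex term, and Hba-a1 was lower with ethanol in both sexes (82.0 to 3.83 CPM in males, 1.18 to 0.346 in females). These globin copies are near-identical, so their counts are uncertain. Cholangiocytes, the bile duct epithelium, had 117 of 11752 genes past the test (87 higher, 30 lower), with Krt17 (5.05), Fosl1 (3.55) and Noct (3.44) higher and Msmo1 (-3.16) and Tmeff2 (-3.11) lower. Mitochondrially encoded genes had 0 of 13 past the test in cholangiocytes, but 12 rose adjusted over the list alone. Immediate early genes rose in 13 of 25 in B cells (Klf4 1.40), 8 of 25 in conventional dendritic and 8 of 25 in NK cells or ILC1, 5 of 25 in cholangiocytes and 4 of 25 in T cells, and fell in 0, 2, 5, 2 and 0. Hepatocyte RNA fell in 5 of 9 genes in B cells, 5 of 8 in NK cells or ILC1, 3 of 18 in T cells and 5 of 10 in plasmacytoid dendritic cells. DESeq2 on all 4 libraries gave 823 calls in NK cells or ILC1, 430 in B cells and 464 in plasmacytoid dendritic cells, fewer than edgeR. Without the ethanol male and the ethanol female library in turn, NK cells or ILC1 gave 965 and 1007 calls, B cells 497 and 252, plasmacytoid dendritic cells 276 and 201, and cholangiocytes 41 and 27, against 263 and 233 for cholangiocytes without the control male and control female. T cells gave 0 calls by edgeR without the control male library (2435 at an unadjusted p under 0.05) and 0 without the control female (2680), 1421 without the ethanol male and 1819 without the ethanol female, against 799 by DESeq2 on all 4. Conventional dendritic cells gave 0 by edgeR without the ethanol male (2783 at an unadjusted p under 0.05), 706 without the control male and 282 without the ethanol female, against 870 by DESeq2 on all 4.

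Because the series title names a gut-liver IgA axis, the heavy-chain transcript of IgA was followed in every library. Igha UMIs numbered 35054, 36253, 38513 and 38742 in control male, ethanol male, control female and ethanol female, or 565, 336, 313 and 347 CPM. They came from few barcodes. Barcodes with at least 100 Igha UMIs numbered 6 of 7887, 11 of 9971, 16 of 12264 and 11 of 10618, shares of 0.0761% (95% interval 0.0279 to 0.166), 0.110% (0.0551 to 0.197), 0.130% (0.0746 to 0.212) and 0.104% (0.0517 to 0.185). These intervals cover counting error only, and with 1 library per group no difference was tested. Among cells kept after doublet removal, a count added after seeing the data, they numbered 0 of 7631, 2 of 9558, 11 of 11650 and 1 of 10140, with the control female at 0.0944% (0.0471 to 0.169) and the ethanol female at 0.00986% (0.00025 to 0.0549). Of the Igha UMIs in kept cells, these cells held 0%, 15.4%, 92.2% and 5.89%. Over all barcodes past the filters, the barcodes with at least 100 Igha UMIs held 96.2%, 94.5%, 93.5% and 92.3%. Jchain was found in 6 of 6, 10 of 11, 15 of 16 and 11 of 11 of them, Xbp1 in 5, 11, 16 and 11, and Mzb1 in 6, 11, 14 and 6, with a median of 2 Mzb1 UMIs in the ethanol female. Of them, 6, 9, 5 and 10 were marked as doublets. Marking took a fixed share of the top scores, 256, 413, 614 and 478 barcodes, while Scrublet's own threshold called 100, 2, 307 and 135. Whether the marked IgA-rich barcodes are doublets was not tested. Among all barcodes past the filters, 1, 1, 7 and 5 held at least 50 and under 200 Igha UMIs. Jchain stood at 254, 136, 197 and 78.6 CPM and Pigr, the polymeric immunoglobulin receptor, at 20.8, 12.8, 9.83 and 10.6 CPM. Of 18 IgA production and homing genes in B cells, 1 rose, 5 fell and 12 did not pass, with 2 rising and 7 falling adjusted over the list alone. In T cells 1 of 21 rose, 6 fell and 14 did not pass, with 2 and 9 adjusted over the list alone, but free RNA could carry 10 of these 21 members.

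Male and female mice were set side by side to ask whether ethanol moved the same genes in both sexes. Genes with a log2 ratio of the same sign in both sexes made up 56.7% in Kupffer cells, 67.7% in the monocyte class, 64.0% in neutrophils and 75.2% in sinusoidal endothelial cells. Pearson's r between male and female log2 ratios was 0.257, 0.523, 0.392 and 0.585 in those classes. In the other classes the same-sign share ran from 62.1% in cholangiocytes to 73.8% in conventional dendritic cells. These correlations run across genes, which are not independent replicates, and compare 1 library with 1 library in each sex. No interaction of sex and ethanol was tested, since each sex has 1 mouse per treatment.

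Sex itself was compared from the same fits, a result added after hepatocytes proved too few. The fits called 542 gene and class pairs, of which 37 were in Kupffer cells, 82 in neutrophils, 131 in plasmacytoid dendritic cells, 102 in B cells and 71 in sinusoidal endothelial cells. Xist, Tsix and Y-linked genes made up 4, 4, 6, 6 and 5 of these, 5 of 5 calls in conventional dendritic cells, 6 of 11 in T cells, 6 of 14 in monocytes, 6 of 55 in NK cells or ILC1 and 5 of 34 in cholangiocytes. Among the genes with the largest differences in each class, Kupffer cells of females carried more Marco (log2 male minus female -6.01 ± 0.47), Cd55 (-4.66) and Cxcl13 (-3.55), and those of males more Il1r2 (4.84). Il1r2 is a fixed neutrophil marker, at 101 and 637 CPM in control and ethanol males and 5.17 and 11.4 in females. Its difference is therefore not separated from neutrophil cells or RNA in the Kupffer class. The 37 Kupffer calls became 1 without the control female, 3 without the ethanol male, 197 without the control male and 5 with RLE size factors. edgeR gave 0 without doublet removal (878 at an unadjusted p under 0.05) and 0 without the treatment term (680), while DESeq2 gave 42. Monocytes of males carried more C1qa (1.93) and those of females more Lpl (-1.58) and Chil3 (-1.12). Neutrophils of females carried more Il23a (-3.88) and Ifit2 (-2.47), and sinusoidal endothelial cells of females more Vcam1 (-2.04) and Oasl1 (-1.87). Cholangiocytes of females carried more Duoxa2 (-4.85) and Tff3 (-3.27). With 2 mice per sex the sexes cannot be separated from differences between single animals, and leaving out the control male, ethanol male, control female or ethanol female library gave 248, 60, 64 and 110 calls. Of the 248, 197 were in Kupffer cells. In that order neutrophils gave 3, 4, 3 and 15 sex calls, plasmacytoid dendritic cells 6, 6, 5 and 5, B cells 6, 6, 8 and 13, and sinusoidal endothelial cells 8, 12, 16 and 11. DESeq2 on all 4 libraries gave 5, 13, 32 and 17 in these classes. In monocytes and cholangiocytes, with 14 and 34 sex calls, DESeq2 gave 11 and 37. There edgeR without the treatment term gave 0 (84 at an unadjusted p under 0.05) and 11, and any library left out gave fewer calls.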

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

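The tests of the endothelial and T cell shares and, for monocytes, the second tests on Kupffer and dendritic cells and the test of depth were chosen after the results were seen, while the other tests on monocytes were written before theirs were seen.

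Neutrophil granule and maturity genes moved apart in the 2 sexes: their median log2 ratio was 0.35 in males and -0.30 in females, a difference of 0.652 (male minus female). Haemoglobin transcripts in B cells had medians of 1.91 in males and -4.73 in females, a difference of 6.64. Each sex has 1 library per treatment, so neither difference between the sexes was tested, and haemoglobin copies are near-identical in sequence.

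Sinusoidal endothelial cells made up less of the ethanol libraries in both sexes. Dilution by T cells was argued against as the whole cause, since among cells that are not T cells the share was still 0.398 of control in the sex with the smaller change. The unnamed cluster led by Iigp1, Cxcl9 and Sele was argued against as the whole cause too, since with it added the share was 0.575 of control at most. Both together left 0.249 of control in males. In females they left 0.979 (10.7% against 10.9%), which cannot decide whether they account for the lower share. Among female cells that are not T cells, B cells made up 56.3% in control and 15.3% with ethanol, which lowers the control share by construction. Whether that cluster belongs to this class is also open. At the coarser clustering, Sele and Iigp1 were leading genes of a cluster named vascular endothelial, which scored 2.47 as vascular and 2.46 as sinusoidal. Poorer recovery of intact endothelial cells cannot be told apart from a loss in the liver, which was not tested: at least 58.4% of the class lay in its low-UMI cluster with ethanol, while the cholangiocyte share was 0.852% and 0.326% in controls and 0.847% and 0.750% with ethanol.

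T cells made up more of the ethanol libraries in both sexes. Loss of the other classes cannot be told apart from more T cells: T cells per NK or ILC1 cell were at least 3.30-fold control, which either would give, and shares hold no absolute cell numbers. More blood left in the liver stays open: the B cell share was 0.759 of control or lower, but T cells dilute it, and among cells that are not T cells B cells were 1.23-fold control in males and 0.272 in females. The Lef1 and Dapl1 T cluster was 1.02-fold and 1.78-fold control, against 4.86-fold and 3.57-fold for all T cells. Differences between single mice and suspensions were not separable from ethanol, and a biological increase of T cells stays open, as untested.

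Monocytes carried more C1q, class II and Gpnmb transcripts with ethanol. A shift between the 2 clusters of the class was argued against, since in the F13a1 cluster alone the median log2 fold change of the 8 genes was 3.26 and 8 of 8 passed, and so was a difference in depth and mitochondrial percentage, since in that cluster median UMIs were 19857.5, 19702.5, 20041 and 19605, mitochondrial medians 1.61, 1.66, 1.29 and 1.74, and the smallest per-sex log2 ratio 2.04. Kupffer cells or their RNA were tested in 2 ways, in this order: the first test, written before its result was seen, gave a marker median of 1.42 from 1 of 10 markers and decided nothing, and the second, chosen after the first came out undecided, found at most 0.18 of the marker UMIs that the C1qa excess needs, 11 and 24 against 227 and 198 in the ethanol male and female. Dendritic cells were tested in the same 2 ways. The first test, also written before its result was seen, gave a median of 0.21 over 7 markers against 2.52 for H2-Aa. It decided nothing, since the markers went both ways, with quartiles of -0.66 and 1.86. Flt3 (2.07), Clec9a (2.27) and Ccr7 (1.65) rose, and Cd209a (-2.48) and Naaa (-1.02) fell. The second test, chosen after that, found 448 and 562 marker UMIs against 1242 and 1465 needed by the H2-Aa excess. That is at most 0.417 with counting error, which argues against dendritic cells as the whole cause and leaves a smaller admixture open. The Cd209a dendritic cluster grew at the coarser clustering while the monocyte class shrank, so the border between these classes is also open.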

How the results depend on the processing

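The mitochondrial term, the shares among cells other than B cells, the libraries left out in the classes outside the 4 focus classes, every alternative of the sex calls and the doublet alternative of the IgA-rich barcodes were chosen after seeing the data. Of the summary values, 209 stayed within their limits and 74 moved under the alternatives set beforehand, and 34 and 48 under added ones. Of the values for single genes under those set beforehand, 1955 kept direction and side of the threshold, 366 lost the call, 16 gained it and 4 reversed. The 1955 include DESeq2 values without an adjusted p, for which only the direction was compared. Libraries left out in the classes outside the 4 focus classes are counted here too, although added, with the reversal of Hba-a1 among them. Under the other added ones, 172 kept direction and side of the threshold, 97 lost the call and 5 reversed.

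The cause was not tested for any change below unless stated. Ethanol calls were 45 in Kupffer cells, 1081 in monocytes, 741 in neutrophils, 3004 in sinusoidal endothelial cells, 1526 in conventional dendritic cells, 2007 in plasmacytoid dendritic cells, 636 in T cells, 2604 in NK cells or ILC1, 1519 in B cells and 117 in cholangiocytes. RLE size factors gave 0 in Kupffer cells by edgeR (654 at an unadjusted p under 0.05, DESeq2 41). Without the low-count filter the calls were 250 in Kupffer cells, 1642 in monocytes, 3155 in conventional dendritic cells, 2275 in T cells and 850 in cholangiocytes. DESeq2 gave 599 in monocytes, 200 in neutrophils, 870 in conventional dendritic cells, 464 in plasmacytoid dendritic cells, 823 in NK cells or ILC1, 430 in B cells and 1382 in sinusoidal endothelial cells. Without the sex term edgeR gave 0 in Kupffer cells (369 at an unadjusted p under 0.05), 297 in neutrophils, 1095 in plasmacytoid dendritic cells, 307 in T cells, 685 in B cells and 1550 in sinusoidal endothelial cells. No doublet removal gave 0 in Kupffer cells by edgeR (688 at an unadjusted p under 0.05), 350 in neutrophils and 279 in cholangiocytes. Resolution 0.5 gave 500 in monocytes and 354 in T cells, and the stricter cell filter 302 in cholangiocytes. Equal cell numbers gave 27 in Kupffer cells, 1101 in plasmacytoid dendritic cells, 652 in B cells and 369 in cholangiocytes. The median mitochondrial percentage in place of sex gave 23 in monocytes, 132 in neutrophils, 1197 in NK cells or ILC1, 297 in sinusoidal endothelial cells and 430 in cholangiocytes. It gave 0 by edgeR in conventional dendritic cells (1279 at an unadjusted p under 0.05, DESeq2 with sex 870) and 0 in T cells (1807, DESeq2 with sex 799). That percentage splits the libraries by treatment in monocytes, neutrophils, sinusoidal endothelial, conventional dendritic, T, NK or ILC1 cells and cholangiocytes, so in these classes, with both counts of 0 among them, it overlaps with ethanol by construction.

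Leaving out each library in turn gave 3 to 288 calls in Kupffer cells, 157 to 942 in monocytes, 169 to 749 in neutrophils, 411 to 2047 in sinusoidal endothelial cells, 0 to 1382 in conventional dendritic cells, 201 to 1973 in plasmacytoid dendritic cells, 0 to 1819 in T cells, 965 to 1782 in NK cells or ILC1, 252 to 1413 in B cells and 27 to 263 in cholangiocytes. The 0 in conventional dendritic cells came without the ethanol male (2783 at an unadjusted p under 0.05), and those in T cells without the control male (2435) and without the control female (2680). These fits use 3 libraries and assume that the lone library of an arm varies like the other arm.

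Sex calls, 542 in total, were 2105 without the low-count filter, 235 by DESeq2, 35 without the treatment term, 354 with equal cell numbers and 60 to 248 with a library left out.

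Share differences, ethanol minus control in percentage points, moved with the stricter cell filter in males to -5.84 for monocytes, -8.71 for neutrophils, 1.94 for conventional dendritic, 3.83 for plasmacytoid dendritic, 36.5 for T, -4.12 for B and -30.9 for sinusoidal endothelial cells. In females it gave 2.40 for conventional dendritic, 39.5 for T, -43.4 for B and -4.91 for sinusoidal endothelial cells. Resolution 0.5 gave 38.0 and 40.2 for T cells, 1.65 and 1.98 for NK cells or ILC1 and 3.71 and 3.10 for vascular endothelial cells, in males and females. Among cells other than B cells, males gave -5.50 for monocytes, -8.83 for neutrophils, 37.9 for T and -41.5 for sinusoidal endothelial cells. Females gave -1.40 for Kupffer cells, -9.64 for monocytes, -5.18 for neutrophils, 1.76 for conventional dendritic, 4.05 for plasmacytoid dendritic, 26.7 for T, -5.77 for NK or ILC1, -15.5 for sinusoidal endothelial cells and 0.179 for cholangiocytes, where removing the B cells of the control female library shrinks its denominator by construction.

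CPM without TMM gave 68.6% of genes with the same sign in plasmacytoid dendritic and 73.9% in sinusoidal endothelial cells. Without members that free RNA could carry, list medians became -0.20 for Fc and IgA receptors in female neutrophils, -0.28 and -0.45 for IgA production in male and female T cells, 0.84 for the lipid-associated, 1.34 for the reparative and 3.0 for the proliferation list in male monocytes, and 0.69 for antigen presentation in female sinusoidal endothelial cells. Immediate early medians became 0.65 in male plasmacytoid dendritic cells, -0.40 in female NK cells or ILC1 and 0.34 in male B cells. Hepatocyte RNA medians became -0.32 in monocytes, -0.035 in sinusoidal endothelial cells and -0.016 in cholangiocytes, all in females. Proliferation medians became -0.21 and -0.27 in male and female NK cells or ILC1 and -0.050 in female B cells. With members at 0 UMIs set to 3 UMIs, 6 of 182 medians moved by over 0.1 and 1 changed sign, haemoglobin RNA in female sinusoidal endothelial cells, from -2.45 to 0.10. Counting kept cells only, IgA-rich barcodes were 0% in the control male, 0.0209% in the ethanol male, 0.0944% in the control female and 0.00986% in the ethanol female, after 6 of 6, 9 of 11, 5 of 16 and 10 of 11 were removed as doublets in control male, ethanol male, control female and ethanol female.

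Single genes that reversed in Kupffer cells with a library left out were Cxcl2 (-0.16 without the ethanol male to 1.79 without the control male), Fcgr2b (-0.067 to 2.92, the same libraries) and Marco (-7.05 without the ethanol female to 2.42 without the control female). The gene Hba-a1 in plasmacytoid dendritic cells also reversed, from -6.83 without the ethanol male to 0.83 without the control male. These fits hold no sex term, and Marco and Hba-a1 differed strongly by sex (log2 male minus female -6.01 and 5.35). Both genes were lower with ethanol within each sex, so their reversals mix sex with ethanol. With the mitochondrial term, Chil3 in monocytes (0.38) and Cd34 (-0.81), Isg15 (-2.68), Ifit1 (-2.08) and H2-D1 (-0.74) in sinusoidal endothelial cells reversed.

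Hepatocyte comparisons and their alternatives were not run, for want of cells. In Kupffer cells the stricter filter and the larger cluster alone left fewer than 30 cells in the ethanol male library, and gave no value. For the shares, the planned denominator without hepatocytes and erythroid cells is not reported for those classes themselves, where it is 0 by construction. No paired analysis was possible because each mouse gave 1 library.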

Other observations

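All tests in this part were chosen after the data were seen, except the gene lists.

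Each T cluster with at least 30 cells in every library was tested alone with edgeR. The Slc28a2b and Lef1 cluster gave 342 genes past the test, including Ston1 (2.95) and Igfbp4 (-1.55), the Atp8a2 and Zbtb16 cluster 812, and the Foxp3 cluster 204, including Mest (4.76). Clusters 12 and 23 gave 520 and 259, including Tgfa (3.82) and Ptprk (-2.92) in the first and Il5 (5.17) in the second. In the control male and control female, Mest stood at 1.87 and 0, Tgfa at 0 and 1.59 and Il5 at 0 and 8.57 CPM. Their folds are therefore uncertain. The Gzmk and Cd8a cluster gave 0 by edgeR, with 1149 of 9540 at an unadjusted p under 0.05, and no other tool was run on it.

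An unnamed cluster led by Iigp1, Cxcl9, Vcam1 and Sele held 5, 317, 27 and 331 cells in control male, ethanol male, control female and ethanol female.

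Mitochondrially encoded genes rose in 4 of 13 in conventional dendritic cells, 1 in plasmacytoid dendritic cells, 3 in NK cells or ILC1, 1 in B cells and 0 in T cells and cholangiocytes, and fell in 0, 0, 1, 2, 2 and 0. Adjusted over the list alone, 12 of the 13 rose in cholangiocytes and 6 fell in T cells. In cholangiocytes all 13 were higher in both sexes, with medians of 0.55 in males and 0.77 in females, at percentiles 99.3 and 100 of matched random lists. Haemoglobin transcripts fell in 3 of 3 genes in conventional dendritic cells and 4 of 4 in NK cells or ILC1, with 0 of 4 past the edgeR test in T cells and in B cells. Neutrophil RNA fell in 2 of 5 genes in conventional dendritic cells, 3 of 5 in plasmacytoid dendritic cells, 2 of 6 in T cells and 2 of 4 in NK cells or ILC1 and in B cells. Proliferation genes rose in 4 of 17 and fell in 2 in NK cells or ILC1, rose in 2 of 13 in B cells and 1 of 10 in plasmacytoid dendritic cells, and without members at the level of free RNA rose in 0 of 9, 2 of 7 and 0 of 6. They had none past the test among 20 in T cells and 18 in cholangiocytes.

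IgA-rich barcodes held median totals of 49778.5, 30753, 21402 and 20661 UMIs, against 5128, 8894, 8766 and 9232 for all barcodes past the filters. At a minimum of 50 Igha UMIs they numbered 6, 11, 21 and 12, and at 200 they numbered 5, 10, 14 and 7.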
